A study of Drosophila melanogaster with 2 samples.

How the data were processed

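ChIP-seq of a CG5953-eGFP fusion protein was measured in whole Drosophila melanogaster embryos aged 0 to 24 h, in 2 libraries that the labels name biological replicates 1 and 2. Per the labels, chromatin was fragmented by sonication to a size range of 200 to 800 bp and the immunoprecipitation used an antibody against green fluorescent protein. Fragments of that length limit how finely a summit can be placed.

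The files used were peak lists on the dm6 assembly, per the text files deposited beside the samples. Those texts call them ranked and thresholded peaks by the irreproducible discovery rate (IDR), a measure of how well the ranks of peaks repeat between 2 lists. Per the same texts, each library had its own ranked and thresholded list, and further lists were derived from both libraries together, 1 of them called conservative. A further file is listed as an input to each list. The aligner, the peak caller and their versions are not given in the sources used here. In every list the authors gave a signal value per peak, whose unit is not stated in the files. The deposited score of each peak rescales the IDR to a range that ends at 1000, and the lowest score in the thresholded lists was 830. The deposited ranked lists also hold the −log10 of the global IDR, and every peak of the 4 thresholded lists had an IDR of 0.01 or less there. Of the ranked peaks that met this limit, 84, 94, 57 and 70 were left out of the conservative set, the optimal set, replicate 1's list and replicate 2's list, for a reason the sources used here do not give. All conservative peaks were rows of the ranked list whose columns hold the signal of a matching peak in each replicate, and all peaks of the second thresholded list of both libraries, called the optimal set here, were rows of the other ranked list. Weak peaks can be among those that passed, and 80 conservative peaks had a signal under 20. The depth of the libraries is unknown, since peak lists hold no reads. Intervals therefore cover only the number of peaks or genes counted.

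Peaks were analysed with Python 3.11.15 scripts using numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with matplotlib 3.10.9 for plots. Summits were placed on the Ensembl annotation of assembly BDGP6 (release 115) and the Release 6 genome sequence, which share dm6 coordinates. Transposable elements and pseudogenes were left out, and 1 conservative peak on an unplaced scaffold was not used. A gene was called bound when a summit lay within 500 bp of any of its annotated TSS. By this rule 1747 of 17947 genes, among them 1573 of 13968 protein-coding genes (11.3%), were bound. Features were assigned in the order promoter, 5' UTR, 3' UTR, coding exon, noncoding exon, intron, intergenic; noncoding exons were added to the planned features because some summits fit no other. Random placements were uniform on the same arm, drawn 1000 times, and their permutation tests were two-sided. Shares have Clopper-Pearson 95% intervals.

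The 40 gene lists (507 gene symbols, of which 492 were found, plus families taken by name pattern or gene class) and the 28 motifs were fixed before the data were examined. Each list of at least 5 genes was tested by a two-sided Fisher's exact test against all other protein-coding genes, or all other genes for noncoding classes, with Benjamini-Hochberg adjustment over the lists. Exact p-values for lists and motifs are from this test. Neighbouring genes can share a peak, so genes are not fully independent in these tests. Motifs were searched on both strands within 100 bp of summits, against 5 control positions per peak, 15075 in all, at the same signed distance from a TSS without a peak within 1000 bp in any thresholded list, or elsewhere on the same arm for summits away from promoters. Words of 7 bases were searched within 50 bp, found on arms 2L, 2R and X (1666 peaks) and tested on arms 3L, 3R and 4 (1349 peaks) with Bonferroni adjustment. Gene length and the trend of promoter share over signal quartiles were tested with 100000 resamples, and arms with an exact binomial test. The threshold was 0.05 throughout.

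Genes were named by a rule fixed before the data were examined: CG5953; the genes nearest to the 25 strongest conservative peaks and any other gene with a TSS within 500 bp of them, except at 1 peak left undescribed; for lists past the threshold, up to 4 bound members with the highest signal; and for lists below expectation, the bound members where 3 or fewer. Bound members of lists that did not pass the test were named after their values were seen. Signal values of the replicates are those of the strongest overlapping peak in each replicate's own ranked list.

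The scripts were tested on simulated data. Lists planted at 4 times the odds were called in 100% of runs and unchanged lists in 0.216% (17947 genes). The planted lists were the mitochondrial ribosomal, respiratory chain and cuticle protein genes, with 75, 87 and 122 genes. Recovery of smaller lists was not tested. Genes were drawn independently in these runs, without peaks shared between neighbours. Randomly placed summits were called enriched or depleted at promoters in 5% of runs, and always when 1 in 10 was moved to a TSS (3015 peaks). Between 2 sets of control positions 0 motifs and 0 words were called, and a planted motif and its word of 7 bases were recovered. Permuted signals gave a trend in 5% of runs and random gene sets a length difference in 0%.

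Alternatives were the optimal set, either replicate's own list alone, the stronger peaks by signal, other windows, assignments, backgrounds, controls, overlap rules and arm splits. Chosen only after seeing the data were placements drawn from ranked peaks that missed the threshold, the removal of peaks of signal under 20, peaks found in both replicates' own lists, controls matched on GC content, and the nearest TSS alone for gene orientation and length.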

Results

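The data described where the protein encoded by CG5953 was found on the genome of fruit fly (Drosophila melanogaster) embryos. Flies carried CG5953 fused to enhanced green fluorescent protein, chromatin was taken from embryos aged 0 to 24 h, and an antibody against green fluorescent protein pulled down the fusion protein with its DNA for sequencing (ChIP-seq). CG5953 (FBgn0032587) lies on the minus strand of chromosome arm 2L, from 16508078 to 16532877 (dm6), and has no named function in the annotation used here. Per the labels, both libraries were biological replicates of this 1 group, so no comparison between groups was possible, and control libraries were not analysed here. The peak lists hold no read counts, so the depth of each library is unknown. The conservative set held 3016 peaks with a median width of 296 bp, covering 849 kb. Its signal values, which are the authors' own value per peak, ranged from 2.01 to 1168 with a median of 83.0. The optimal set held 3305 peaks, replicate 1's own thresholded list 1975 and replicate 2's own list 1663. All further values are for the 3015 conservative peaks on the chromosome arms unless another set is named.

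The first question was how well peaks repeated between the replicates. Of replicate 1's own peaks, 61.1% (1206 of 1975; Clopper-Pearson 95% interval 58.9 to 63.2%) overlapped a peak of replicate 2 by at least 1 bp. In the other direction 71.6% of 1660 placed peaks (69.3 to 73.7%) overlapped a peak of replicate 1. Shuffled positions gave 0.654% and 0.756%, and the permutation p was 0.002 in both directions, the smallest that 1000 shuffles can give in a two-sided test. Across the conservative peaks, the signals of the matching peaks in the 2 replicates had a Spearman correlation of 0.626 and a Pearson correlation of 0.798 on the log2 scale, and they differed by a median of 1.26-fold. These peaks passed a threshold on how well their ranks repeat between the replicates, so the correlations and the difference hold for peaks selected on that and do not measure how well signals repeat in general. Peaks are also not independent replicates. Of the conservative peaks, 1181 overlapped a peak in both replicates' own thresholded lists, 521 a peak of replicate 1 alone, 329 a peak of replicate 2 alone, and 984 a peak in neither.

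The tagged protein was found mainly at promoters and within introns, and rarely in coding exons. Of the peak summits, 45.3% (1365 of 3015; 43.5 to 47.1%) lay within 500 bp of an annotated transcription start site (TSS), against 13.5% ± 0.641 (SD of 1000 draws) for random placements on the same arms, a ratio of 3.36. The replicates' own lists gave promoter shares of 47.2% and 50.7%, or 49.0% ± 2.50 (SD, n = 2). Introns held 35.8% of summits and intergenic DNA 13.6%, against 39.3% and 27.6% of random placements. Coding exons held 2.72% against 13.1%, and 3' UTRs 0.862% against 5.03%; the replicates' own lists held 0.911% and 1.45% of summits in coding exons. The promoter excess and these 4 deficits passed the test (permutation, adjusted p = 0.0035, and 0.0056 for introns), whereas 5' UTRs (0.829%) and noncoding exons (0.962%) did not pass. The replicates' own lists held 0.354% and 0.542% of summits in 5' UTRs, and 6 features passed with replicate 1's own list. The intron deficit was lost (permutation, adjusted p = 0.478) when positions were drawn from ranked peaks that missed the threshold, an alternative chosen after seeing the data, whereas the promoter excess remained, at 2.91 times the 15.5% of such positions.

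**Figure D1:**
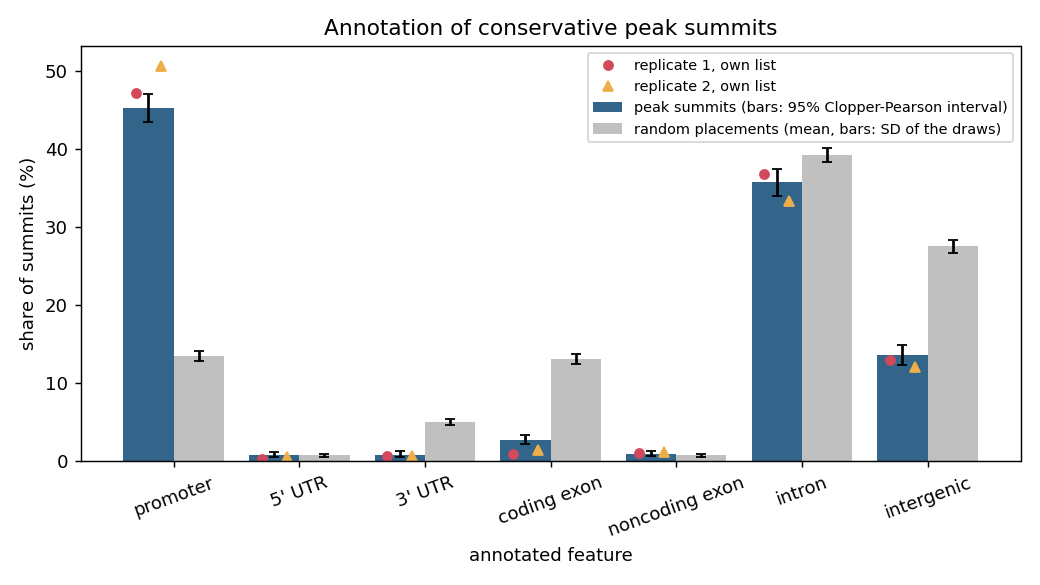
Share of conservative peak summits (%, blue bars with Clopper-Pearson 95% intervals) in each annotated feature, beside the mean of 1000 random placements (grey bars with the SD of the draws), with circles and triangles for the 2 replicates' own peak lists. Promoters held 45.3% of summits against 13.5% of random placements, and coding exons 2.72% against 13.1%.

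Promoter summits lay mostly just upstream of the TSS. Of the 1365 promoter summits, 70.8% (68.3 to 73.2%) were upstream, and the median position was 82 bp upstream, with quartiles at 171 bp upstream and 22 bp downstream. The summits outside promoters lay a median of 2.48 kb from a TSS. Stronger peaks were more often at promoters. The promoter share was 38.1% in the quartile with the lowest signal, 42.6% and 44.2% in the middle quartiles and 56.2% in the quartile with the highest signal (permutation test for trend, p = 1e-05, the smallest that 100000 resamples can give).

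**Figure D2:**
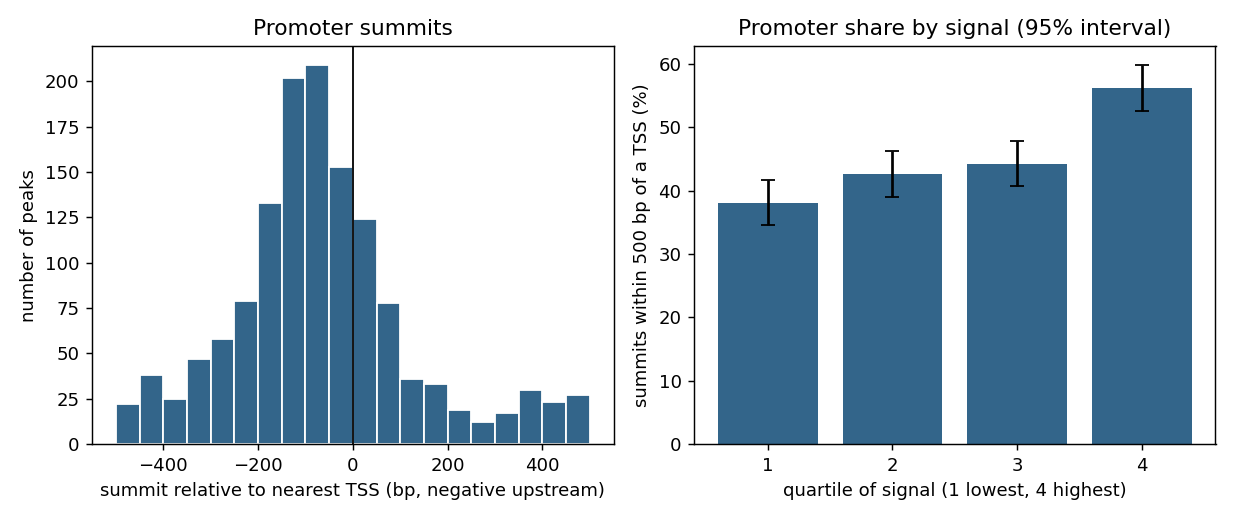
Left, number of promoter summits by position relative to the nearest TSS (bp, negative upstream, 50 bp per bar), with the highest bar, 209 summits, from 100 to 50 bp upstream. Right, share of summits within 500 bp of a TSS (%, bars with Clopper-Pearson 95% intervals) by quartile of the authors' signal, from 38.1% in the lowest to 56.2% in the highest.

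The strongest peaks lay mostly at promoters. The highest signal, 1168, was at the promoter of Ugalt (FBgn0024994), a UDP-galactose transporter of the Golgi, at X, 2703756 to 2704025, where the replicates' own signals were 655 and 524. The next were at the promoter of CG14100 (3L, 19590480 to 19590736; signal 1152) and in an intron of CG11050 (2L, 6612594 to 6612856; signal 1009). The promoter of mRpL41, a mitochondrial ribosomal protein gene, ranked next (2R, 15217639 to 15217872; signal 921), with the TSS of lncRNA:CR44463 also within 500 bp. After it came a peak in an intron of ph-p, a Polycomb group gene (X, 2137247 to 2137466; signal 837).

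Among the 25 strongest peaks, 18 were at promoters, 5 in introns and 2 between genes, and all 25 had a peak in both replicates' own thresholded lists. The median distance of the 18 promoter summits from the TSS was 98 bp. Genes with mitochondrial products among them were PNPase (signal 815), a mitochondrial polynucleotide phosphorylase, CIA30 beside CG7601 (790), a respiratory complex I assembly factor, mRpS23 beside CenG1A (763), mRpS10 beside Art3 (727) and mRpL23 beside CG9004 (616). Chromatin genes were Chro, encoding Chromator, with Ssl1 (657), and HmgZ and HmgD, whose peak lay in an intron (714). Other promoters were those of CG8320 and the peroxisome gene Pex11ab (795), CG18549 (722), and Tcs5 and the ESCRT gene CHMP2B (704). The translation factor gene eIF6 shared its peak with asRNA:CR45928 (681). Further promoters were those of px (680), Fkbp14 (629), Rtnl1 (593), and Elp5, an Elongator subunit gene, with CG1275 (569). An intron of CG32772 (620) and an intron of CG32486, with CG16753 as the nearest TSS (586), also carried a peak. Between genes, peaks lay 11907 bp from the nearest TSS, that of CG13323 (827), and 895 bp from lncRNA:CR45643 (718).

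Genes for the cytosolic ribosome carried a peak far more often than other genes. A summit lay within 500 bp of a TSS for 51 of 93 cytosolic ribosomal protein genes (54.8%; 44.2 to 65.2%), against 11.0% of all other protein-coding genes (odds ratio 9.86, Fisher's exact test, Benjamini-Hochberg adjusted p = 3.73e-23). The replicates' own lists gave 47.3% and 46.2%, or 46.8% ± 0.760 (SD, n = 2). The strongest were RpL7 (2L, 10200967 to 10201093; signal 320), RpS27 (3R, 25247440 to 25247600; 306), RpS28b (X, 9554513 to 9554649; 262) and RpL24 (2L, 13395084 to 13395171; 256), each with its summit 5 to 47 bp from the gene's TSS. Glycolytic genes were also bound more often, 6 of 12 (odds ratio 7.91, exact adjusted p = 0.00511), with Gapdh2 (signal 514), Eno (196), Hex-A (173) and Ldh (122) the strongest. Genes of insulator and architectural proteins followed, 8 of 18 (44.4%; odds ratio 6.33, exact adjusted p = 0.00224), led by Chro (657), Trl (185), which encodes GAGA factor, Cp190 (179) and Dref (113), whose summit lay nearer to the TSS of RpL13. The glycolysis call was lost with a 250 bp window (3 of 12, exact adjusted p = 0.194). The insulator call was lost with either replicate's own list (4 of 18 and 5 of 18, exact adjusted p = 0.136 and 0.0537) and with peaks found in both lists (adjusted p = 0.0605), the last an alternative chosen after seeing the data.

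Other large gene families with basic functions did not share this excess. Peaks were found at 11 of 75 mitochondrial ribosomal protein genes (14.7%), 10 of 51 translation factors (19.6%), 6 of 87 respiratory chain and ATP synthase genes (6.90%), 1 of 48 proteasome genes (Rpn3) and 0 of 8 CCT chaperonin genes, and none of these lists passed the test (exact adjusted p = 0.103 to 0.871). Proteasome genes were called lower with a 1000 bp window (exact adjusted p = 0.0371). Translation factors passed it with replicate 1's own list (exact adjusted p = 0.0347) and with the stronger peaks (adjusted p = 0.0263). DNA replication genes (8 of 32, exact adjusted p = 0.0753; 2 and 4 of 32 with the replicates' own lists), heat shock proteins and chaperones (7 of 27, adjusted p = 0.0758) and cell cycle genes (5 of 30; 3 and 1 with the replicates' own lists) did not pass, although the chaperones did (adjusted p = 0.0207) when each peak counted only for its nearest TSS. Polycomb and Trithorax group genes were bound in 6 of 28 cases, among them ph-p, brm and E(z), and snRNA genes in 6 of 32.

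Among the lists of developmental regulators and tissue markers, only cuticle protein genes, described below, stood apart from other genes. Peaks lay at 4 of 36 Hox and segmentation genes (fkh, odd, cad and Dfd), 2 of 23 dorsoventral patterning genes and 1 of 20 neural progenitor genes. Of the other tissue markers, 2 of 29 neuronal effector genes, 3 of 29 muscle genes, 2 of 14 tracheal genes, 1 of 13 fat body genes, 4 of 18 germline genes, 0 of 17 hemocyte genes and 0 of 14 midgut and yolk genes were bound. Among signalling pathways the counts were 6 of 27 for EGFR and FGFR, 4 of 22 for Notch, 3 of 24 for Wnt, 1 of 12 for Hedgehog, 2 of 18 for TGF-beta, 1 of 10 for JAK-STAT, 1 of 18 for ecdysone and 5 of 27 for innate immunity. Counts for such small lists varied between the replicates' own lists, with 1 and 2 Hox and segmentation genes, 5 and 3 EGFR and FGFR genes, 2 and 6 innate immunity genes and 0 and 1 tracheal genes. None of these lists passed the test (Fisher's exact test, adjusted p of at least 0.258), but small lists have wide intervals, reaching 47.6% for the 18 germline genes. With a 1000 bp window, 9 of 27 EGFR and FGFR genes were bound and the list passed (exact adjusted p = 0.0292).

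Several large gene families and most noncoding classes carried a peak within 500 bp of an annotated TSS less often than other genes. No peak lay at any of 180 chemoreceptor genes (interval up to 2.03%, exact adjusted p = 8.37e-09) or 111 genes of the histone cluster (interval up to 3.27%, adjusted p = 2.73e-05), and 1 lay at 51 odorant binding protein genes (adjusted p = 0.0758, or 0.0292 with a 1000 bp window). Cuticle protein genes were bound in 2 of 122 cases (1.64%, exact adjusted p = 0.000852), namely Cpr73D, which shares its peak with Ogdh, and Cpr65Av, neither with a peak in both replicates' own lists. Cytochrome P450 genes were bound in 2 of 83 cases (2.41%, exact adjusted p = 0.0280), Cyp6u1, which shares its peak with Ufsp1, and Cyp4e2, whose peak was not in both replicates' lists. Among all annotated genes, 84 of 1945 long noncoding RNA genes (4.32%, exact adjusted p = 2.26e-19), 8 of 260 miRNA genes (3.08%, adjusted p = 0.000414), 13 of 269 snoRNA genes (4.83%, adjusted p = 0.0215) and 15 of 290 tRNA genes (5.17%, adjusted p = 0.0267) were bound, against 9.81 to 10.4% of other genes. The replicates' own lists, which hold fewer peaks, gave 1.15% and 1.54% for miRNA genes, 3.03% and 2.72% for long noncoding RNA genes and 4.14% and 1.38% for tRNA genes. The strongest of these peaks lay at lncRNA:CR44463, which shares it with mRpL41, and at lncRNA:CR31840 (signal 542), lncRNA:CR31044 (519) and lncRNA:CR44810 (498), and the strongest snoRNA peak (188) lay nearest to the TSS of the snoRNA host gene Uhg4. Calls for cytochrome P450, snoRNA and tRNA genes were lost under several alternatives, and histone and tRNA genes exist in near-identical copies, where reads are hard to place. The TSS was the start of the annotated transcript, so a peak at a host gene's promoter counts for a snoRNA or miRNA only within 500 bp. The bound share of snoRNA genes was 1.86% with a 250 bp window and 15.6% with a 1000 bp window. Low shares of these classes therefore depend on where their TSS is annotated.

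**Figure D3:**
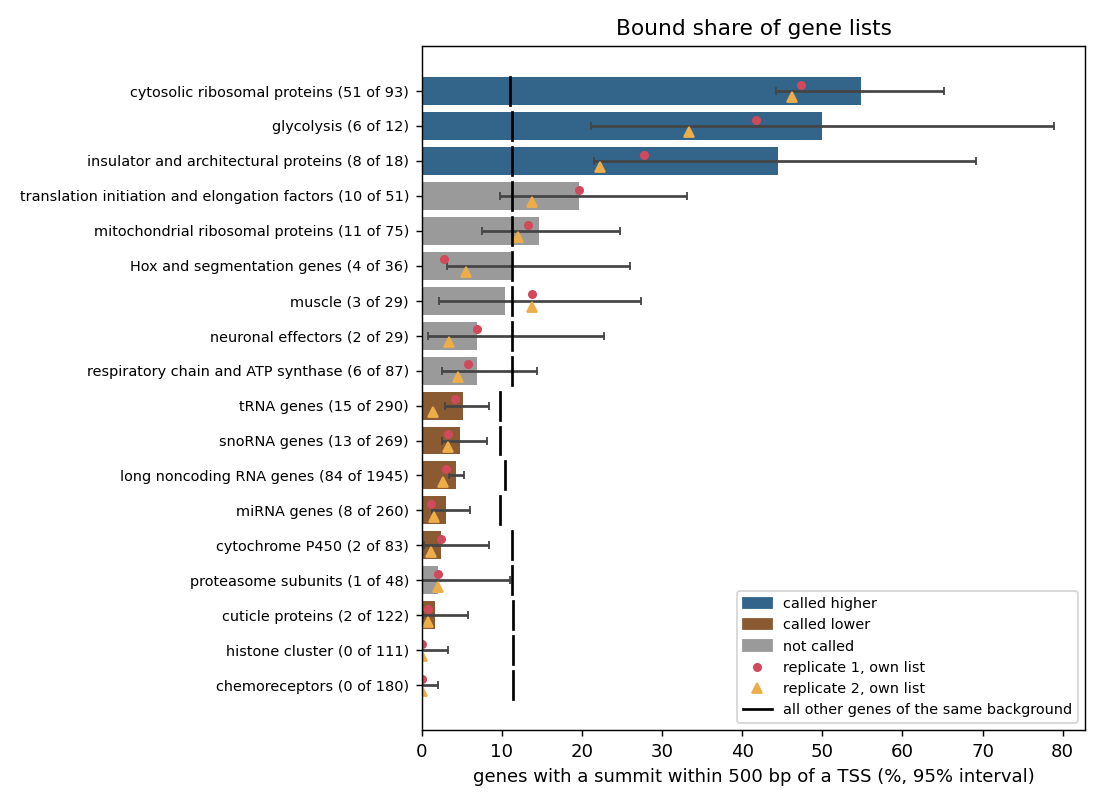
Share of genes with a summit within 500 bp of a TSS (%, bars with Clopper-Pearson 95% intervals) for the 11 lists past the threshold and 7 others, with the number bound of the number in each list, black lines for all other genes of the same background, and circles and triangles for the 2 replicates' own lists. Cytosolic ribosomal protein genes stand at 54.8% against 11.0%, and the proteasome genes at 2.08%.

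Bound genes often stood head to head with a neighbour and were longer than unbound ones. Of 1573 bound protein-coding genes, 59.1% (56.6 to 61.6%) had a TSS within 1 kb head to head of another protein-coding TSS, against 33.3% (32.4 to 34.1%) of 12395 unbound genes (odds ratio 2.90, Fisher's exact test, p = 4.58e-86). A summit between divergent TSS can count for both genes. With each peak counted only for its nearest TSS, an alternative chosen after seeing the data, the shares were 47.8% of bound and 35.1% of unbound genes (odds ratio 1.69, Fisher's exact test, p = 1.57e-17). The median length of bound genes was 3.52 kb (quartiles 1.80 and 9.56 kb), against 2.05 kb (1.12 and 4.58 kb) for unbound genes (permutation p = 1e-05, the smallest that 100000 resamples can give). A gene with more annotated TSS has more places where a summit counts, and the number of TSS per gene was not matched in either comparison.

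Peaks were spread over the large arms and nearly absent from the small ones. Chromosome 4 held 8 peaks, 0.273 times the number expected from its length (exact binomial test, adjusted p = 2.27e-05) and 0.354 times that expected from its TSS. The Y chromosome, 2.49% of the assembled length, held none. No peak can be called where reads cannot be placed, and how much of each arm this affects was not assessed, so an absence of peaks is not an absence of binding. Arm 2L held 591 peaks, 1.14 times the expectation from length (exact binomial test, adjusted p = 0.00107). This excess was absent when TSS were the reference (ratio 1.01), and it was lost with the optimal set and with either replicate's own list. By that reference arm 3L held more peaks than expected (650 peaks, ratio 1.12, exact binomial test, adjusted p = 0.00624). The X chromosome did not pass by length (502 peaks, ratio 0.972).

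The sequence around the summits was compared with unbound positions. For promoter summits these were matched for distance to a TSS, and for the others they were random positions elsewhere on the same arm. The latter were not matched on feature, although coding exons held 2.72% of all summits against 13.1% of random placements. How much this moved the frequencies of motifs and words was not tested. Of 28 motifs fixed before the data were examined, 12 were more frequent within 100 bp of a summit and 3 less frequent. GA repeats of the kind bound by GAGA factor were found at 5.31% of summits against 2.71% of controls (odds ratio 2.01, Fisher's exact test, adjusted p = 1.07e-10), and the core of the CTCF site at 2.16% (odds ratio 2.05, adjusted p = 2.39e-05). The housekeeping promoter element Motif 7 (10.7% against 7.30%), the AT-rich Mef2-type site (10.4% against 6.92%) and the ETS-type site (1.69% against 0.949%) were also more frequent. The Pho site (10.3% against 13.7%, exact adjusted p = 2.75e-06), the initiator (16.5% against 19.6%) and the Tramtrack-type site (1.16% against 2.00%) were less frequent, whereas the DREF site (2.29% against 1.89%) and the Zelda site (4.11% against 4.54%) did not pass the test. The Zelda site was less frequent with the optimal set and with replicate 1's own list (odds ratios 0.806 and 0.712), and the DREF site more frequent with replicate 2's own list (1.58). Calls for Motif 7, CTCF, ETS, Mef2 and Pho held under all 10 alternatives, and that for GA repeats was lost only within 50 bp of the summit (odds ratio 1.10). The other 9 calls were each lost or turned under at least 1 alternative, and the Zeste site was called less frequent with replicate 1's own list (odds ratio 0.861). With replicate 2's own list the odds ratios were 3.64 for CTCF and 2.87 for ETS.

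Among all 8192 words of 7 bases, 30 were enriched within 50 bp of summits on arms 2L, 2R and X, and 19 of these were enriched again on arms 3L, 3R and 4. They fell into AT-rich words with at most a single G or C (15 of the 19), such as AAATAAT (12.2% against 7.12% of controls on the test arms, Fisher's exact test, Bonferroni p = 8.88e-08), and words containing CAGTG (4). The CAGTG words were ACAGTGG (3.41% against 1.23%, exact Bonferroni p = 4.01e-06), CAGTGCA (3.85% against 1.68%, p = 6.61e-05), CAGTGTA and CACAGTG. Summits were richer in A and T than the controls, with a median GC content of 37.8% against 41.8%. With controls also matched on GC content, an alternative chosen after seeing the data, 6 words held, 5 of them containing CAGTG. With only the 1181 peaks in both replicates' own lists, also chosen after seeing the data, 8 words held and 0 of them contained CAGTG. With a window of 100 bp, 56 words held, 12 of them containing CAGTG, and ACAGTGG was then found at 9.12% of the test summits against 2.64% of controls.

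At CG5953, the gene whose protein was tagged, 4 conservative peaks lay within 5 kb. The labels describe transgenic flies expressing the fusion protein, and where the fusion gene was inserted was not established here. The fusion gene may itself give signal at this locus, so these peaks cannot be read as binding of the protein to its own gene. The stronger ones lay upstream, at 2L, 16533201 to 16533312 (promoter, 404 bp from the TSS; signal 218, rank 258 of 3016) and at 2L, 16535822 to 16536117 (intergenic; signal 213, rank 268), and both replicates' own lists held peaks there. The intergenic summit lay 742 bp from the nearest TSS, which is not that of CG5953. The others lay in an intron (16521313 to 16521608; signal 76.0, rank 1731) and at the promoter (16532656 to 16532951; signal 58.1, rank 2625), and neither was in the replicates' own thresholded lists. In replicate 1's list the highest rank of a peak at the locus was 188 of 1975 and in replicate 2's list 386 of 1663.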

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

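Of 99 alternative values for the main results, 88 kept their direction and side of the threshold, stayed within 1.5 times a count or, for the correlation, within its 95% interval (0.603 to 0.649); the alternatives without weak peaks, with peaks in both replicates' lists, with GC-matched controls, with placements from peaks that missed the threshold and with the nearest TSS for orientation and length were chosen after seeing the data. The promoter share kept its excess under all 9 alternatives (35.4 to 56.9%, the extremes set by the window), as did divergent promoters, gene length and the trend with signal under theirs. Leaving out a replicate gave promoter shares of 47.2 to 50.7%, 5 to 6 lists called lower in place of 8, and 2 to 7 motifs called less frequent in place of 3. Motifs called less frequent were 5 with the optimal set and 5 with the stronger peaks, and motifs called more frequent were 7 within 50 bp in place of 12. With GC-matched controls 8 motifs were called more frequent, a count still kept by the limit of 1.5 times. Of the words of 7 bases, 19 in the main test, 56 held within 100 bp, 12 with the arms exchanged, 8 with peaks in both replicates' lists, 0 of which contained CAGTG, and 6 with GC-matched controls. The Spearman correlation between replicates was 0.548 over the optimal set and 0.570 over the stronger peaks, against 0.626. The bound share of snoRNA genes turned higher than that of other genes with a 1000 bp window (15.6%), without passing the test (exact adjusted p = 0.237). Odds of the Zeste site were 0.998 within 50 bp and 0.861 to 1.23 when a replicate was left out; odds of CA repeats were 0.814 to 1.44 when a replicate was left out, 0.974 with the stronger peaks, 0.898 with peaks in both lists and 0.934 within 50 bp. Of 11 calls on gene lists and 15 on motifs, 6 and 5 held under every alternative run. For each of these changes the cause was not tested; the replicates' lists and the peaks in both hold fewer peaks. Replicate overlap and correlation need both replicates, so neither was recomputed without 1 of them. No paired analysis was possible because there was a single group. Without read depth, weak binding below the threshold cannot be told from none.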

Other observations

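The tests of mitochondrial ribosomal signal, pooled housekeeping genes, GC content, diverged copies and weak peaks were chosen only after those results were seen; the predictions on matched genes, on words at ribosomal protein genes, on peaks ranked over 1000 and on close copies were written before their own values were seen, the last after a first test, on soft-masked bases, had been seen. Mitochondrial ribosomal protein genes were not bound more often than other genes, but those that were bound carried strong peaks. The 11 bound members had a median signal of 270 against 94.2 for other bound protein-coding genes (permutation test, adjusted p = 0.00136 over 17 lists with at least 5 bound members), with mRpL41, mRpS23, mRpS10 and mRpL23 among the 25 strongest peaks. No other list passed this test, cytosolic ribosomal protein genes included (median 118, permutation, adjusted p = 0.162). The hypothesis that the protein binds a subset of mitochondrial ribosomal promoters strongly was drawn from the same peaks and may not hold elsewhere. Neighbours share some of these peaks, such as CenG1A that of mRpS23 (763) and Art3 that of mRpS10 (727).

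Cytosolic ribosomal protein genes differed from other bound genes in where the summit lay. The 51 promoter peaks at these genes had a median distance of 28 bp from the nearest TSS, against 129 bp for 1314 other promoter peaks (permutation p = 6e-05). This comparison was not planned and no prediction was written for it, so its p-value is that of an exploratory test on the same peaks.

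The frequent binding of cytosolic ribosomal protein genes, 54.8%, was set against 3 explanations. Genes matched on length and on the number of neighbouring TSS were bound in 11.1% of cases on average over 1000 draws and in at most 22.0%, which argues against short genes in dense regions as the cause (91 of the 93 genes could be matched). Proteasome, respiratory chain, mitochondrial ribosomal, CCT, glycolytic and translation factor genes together were bound in 12.1% of cases (34 of 281; 8.53 to 16.5%), which argues against a property shared by all housekeeping genes, although 6 of the 12 glycolytic genes were bound. Unspecific signal at the most transcribed promoters stays open: a CACAGTG, TACACTGA or CACTGAGA word lay within 120 bp of 5.88% of the ribosomal protein summits (3 of 51) against 15.4% of other promoter summits in the same bins of signal, a difference that missed the threshold (permutation p = 0.06), and neither expression nor control libraries were analysed here. The prediction had named Fisher's exact test, whereas this p-value came from 10000 draws within the bins of signal. No biological explanation was tested, since the design has a single group.

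Of words containing CAGTG on either strand, 3 were found to have a direction. No word containing CAGTG held in the test on peaks in both replicates' own lists. The 3 words share no direction of CAGTG itself: CACAGTG read inward with CAGTG forward, TACACTGA and CACTGAGA with CAGTG reversed. CACTGAG, which begins CACTGAGA, did not hold in the main test (Fisher's exact test, Bonferroni p = 0.402). ACAGTGG and CAGTGCA, which did hold there, were not examined for direction. In the 1000 strongest peaks, 280 copies of CACAGTG, TACACTGA and CACTGAGA lay 30 to 120 bp from the summit and 20 lay nearer. Those 20 in 1000 peaks compare with 148 in 15075 controls, so the words were not rare at the summit against controls. In the 2015 peaks ranked over 1000, 274 lay 30 to 120 bp away and 53 nearer. The flanking words mostly read towards the summit from either side: on the left as written, on the right as CACTGTG, TCAGTGTA and TCTCAGTG. Of 280 such flanking words 238 (85.0%) read inward, at a median distance of 80 bp, and 30 peaks had inward words on both sides, spaced by a median of 166 bp; over all 3015 peaks 46 did, where 14.5 were expected from independent sides. In the 1000 strongest peaks the arrangement on both sides came mainly from CACAGTG, with 23 peaks against 4.01 expected, whereas TACACTGA and CACTGAGA each had 1 such peak; in the peaks ranked over 1000 the counts were 8, 3 and 3, against 1.19, 0.333 and 0.492 expected. In the control positions 49.8% of flanking words read inward, but their centres were not summits, so no direction was to be expected there. The pattern was found in the 1000 strongest peaks, so the 85.0% describes it and does not test it. At the Rtnl1 promoter, for example, the stretch at 2L, 4997574 to 4997752, 179 bp around the summit at 4997651, begins with CACAGTG and ends with CACTGTG: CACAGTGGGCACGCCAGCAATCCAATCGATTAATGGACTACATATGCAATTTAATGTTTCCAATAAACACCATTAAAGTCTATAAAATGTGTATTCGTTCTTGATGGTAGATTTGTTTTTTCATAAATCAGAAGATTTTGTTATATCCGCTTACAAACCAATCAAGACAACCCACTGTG. Words at a peak in an intron, with prage as the nearest gene (words spanning X, 1830668 to 1830848; signal 353), and at the promoter of PAN3 (words spanning 3L, 3081331 to 3081519; signal 441) have the same arrangement. These examples were chosen after their sequences were seen.

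This inward arrangement was set against technical explanations. In the 2015 peaks ranked over 1000, whose words had not been looked at for direction, 79.2% of 274 flanking words read inward (73.9 to 83.8%), and 16 peaks had them on both sides where 4.95 were expected, so chance placement is not enough. Close copies of a repeated element are argued against by the 3.14% of 510 peaks with a word (16; interval up to 5.04%) that shared a 20-base sequence, low-complexity ones aside, with another of them; soft-masked bases lay near 93.1% of peaks with a word and 88.7% of others (odds ratio 1.72, Fisher's exact test, p = 0.00256), so diverged copies stay open. In controls matched on GC content 52.6% of flanking words read inward (48.0 to 57.1%). Their centres were not summits, so no direction was to be expected there at any GC content. This comparison therefore cannot decide whether GC content plays a part, and how composition changes along the sequence was not matched. Inward words on both sides were found in only 46 of the 3015 peaks, and no biological explanation was tested.

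The 80 conservative peaks with a signal under 20 stand apart from the rest. Of these, 96.2% (77 of 80; 89.4 to 99.2%) had their summit within 300 bp of a ranked peak with over double their signal, at a median distance of 203 bp. In 1000 draws of equally weak ranked peaks that missed the threshold, 31.2% did on average and at most 43.8%. The weak peaks may therefore be shoulders of stronger peaks; this was tested after the pattern was seen, and how they passed the threshold was not tested. Removing them ended none of the calls on features, arms, lists, motifs or words.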
